A study of Mus musculus with 8 samples.

How the data were processed

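Liver sinusoidal endothelial cells (LSECs), the fenestrated cells that line the liver's capillaries, were taken from C57BL/6J mice that were 8 weeks old when they started on either a chow diet or the FFC diet, the diet used to induce non-alcoholic steatohepatitis (NASH), for 24 weeks. Per the labels' protocols, livers were dissociated with enzymes, red cells were lysed, debris was removed, and cells were captured with magnetic beads against CD146, a surface protein of endothelial cells. RNA was extracted straight from the fresh cells (1 protocol line speaks of liver RNA, which the isolation line contradicts), libraries were made from 200 ng of total RNA with a TruSeq v2 kit, and they were sequenced as paired 100-nt reads on a HiSeq instrument. There were 4 libraries per diet. The labels number them but do not say that each came from a separate mouse, so p-values measure the spread between these libraries, which could be in part technical.

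The deposited table held, per the file headers, a raw count and an RPKM value for each of 43346 genes in each of the 8 libraries. The submitters' processing notes name bcl2fastq, STAR 2.6.1, Subread and featureCounts, and the genome build mm10. The aligner and counter options, the annotation release and the strand setting are not given in the sources used here. Reads of overlapping or antisense genes may therefore be mixed, and members of multigene families (the Mup, Cyp2c, Serpina1 and alpha-globin genes, for example) could share or lose reads. The authors' deposited counts were used for every test. The RPKM columns, which the authors deposited beside them, were used only to recover the library total behind each value, which was 2.37 to 2.60 times the sum of the gene counts. Mitochondrial genes were listed at 0 counts in all 8 libraries, so no mitochondrial share could be used as a sign of RNA quality. Symbols are those of the table, some of which are older names (Emr1, Eltd1, Irg1, Ppap2b), and 42462 gene IDs were found in a reference table of names. In the table, 58 symbols named more than 1 gene and were kept apart by gene ID, and 3 unnamed rows held 0.001% of the counts. Coordinates are those of the deposited table, on mm10.

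Total counts per library ran from 16308035 to 20657580 in Chow and from 19037210 to 23335467 in FFC. Libraries were compared in pairs before any averaging. The lowest chi-square per degree of freedom between any 2 libraries was 25.5, so none was a repeat of another.

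Genes were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr with the diet as group, TMM normalization, glmQLFit with robust estimation and glmQLFTest, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. CPM values are TMM-scaled, and standard errors (SE) of log2 fold changes were derived from the quasi-F statistic. Before the data were examined, 28 pathway lists and 18 cell type lists (850 entries, of which 8 were not in the table) were fixed. Lists with at least 5 tested members, 44 of the 46, were tested with camera from limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the 44 lists, and again with camera at an estimated correlation and with fry. Camera asks whether a list's members rank above or below the other genes, and fry whether they move on balance in 1 direction. Similarity of libraries was described by principal components of log2 CPM (prior count 2) of the 500 most variable genes and by Spearman correlations.

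Genes are named by a rule fixed before the data were examined. It takes the 10 largest increases and the 10 largest decreases among genes past the threshold with a mean of at least 5 CPM and groups that do not overlap, leaving out predicted genes and antigen receptor segments. It also takes, for each list, up to 4 members with the smallest adjusted p among those past the threshold with a mean of at least 1 CPM, or the 2 most abundant members where fewer than 2 passed. Vcam1, Stab2, Lyve1, Cd34, Pecam1, Klf2, Nos3 and Alb are named in any case. This gave 166 genes, not all of which are printed, and 1 gene with a library that stood apart from its group is counted but not reported here. Named outside the rule, after their values were seen, are Ccl24, Cxcl13, Hspa1a, Hspa1b, Dnase1l3, Oit3, Stab1, Hp, Trf, Ttr, Fga, Exoc3l2 and Bcl6b. Where a group had 1 to 3 counts in all, a ratio of counts with its exact 95% interval is given, which covers counting error only, since reads without molecular identifiers are not independent molecules.

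The alternatives planned before the data were examined were RLE and upper-quartile factors, library size alone, DESeq2 1.42.0, limma voom, 2 other filters, 2 fold thresholds, the replicate number as a block, a hepatocyte or a macrophage marker score as a covariate, removal of cell type markers and of genes above 5% of a library before normalization (no gene was above it), and leaving out each library in turn. Scaling to 25 pan-endothelial genes, leaving out Chow libraries 3 and 4 together, and a score of lipid-associated macrophage genes as a covariate were added after the data had been seen. The procedure was tested on simulated counts drawn from the means, dispersions and library sizes of the FFC and Chow libraries, with 200 changed genes. In the 15457 simulated genes that passed its filter, edgeR recovered 4.0% of the 1.5-fold, 46.0% of the 2-fold and 92.0% of the 4-fold changes, and 3.1% of its calls were unchanged genes. DESeq2, run on 15621 simulated genes, recovered 18.0%, 69.0% and 98.0%, with 25.7% of its calls unchanged genes, and limma voom recovered 4.0%, 40.0% and 92.0% with 3.3%. Most of the simulated 1.5-fold changes were thus missed. With only 200 changed genes the adjusted threshold is stricter than in the real data, where 2444 genes passed, 1534 of them by at least 2-fold. The shares recovered therefore do not carry over to the real test.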

Results

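Bulk RNA-seq gene counts were available for 8 libraries of liver sinusoidal endothelial cells isolated with CD146 beads, 4 from chow-fed control mice and 4 from mice fed the FFC diet for 24 weeks. The libraries held 16308035 to 23335467 counts over genes, and 15621 genes were tested. The 50 most abundant genes took 11.86% to 16.19% of a library. Per the series record, the study compares the transcriptome of these cells between NASH and control mice. Vcam1 was named before the data were examined because published work from this study is remembered to concern it, which no label states.

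The libraries separated by diet. The first principal component held 68.7% of the variance of the 500 most variable genes, with the Chow libraries between -37.7 and -24.9 and the FFC libraries between 20.5 and 41.7. FFC replicate 2 lay nearest to Chow, at 20.5, and its Spearman correlation with Chow replicate 1 was 0.966, against 0.894 for FFC replicate 4 with the same library. The second component, 17.4%, spread the Chow libraries, from 27.6 in replicate 1 to -23.7 in replicate 3.

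**Figure D1:**
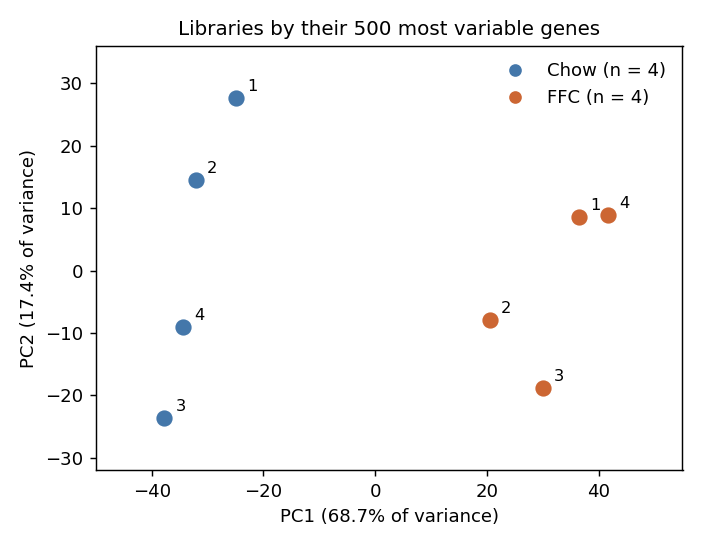
Scores of the 8 libraries on the first (x axis, 68.7% of variance) and second (y axis, 17.4%) principal component of log2 CPM of the 500 most variable genes; each point is 1 library, numbered by its replicate. The FFC libraries lie at 20.5 or above on the first component and the Chow libraries at -24.9 or below, with FFC replicate 2 nearest to Chow.

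In FFC, lists of recruited and lipid-handling macrophages, neutrophils, chemokines and cytokine response ranked higher by camera at its preset correlation. Those of Kupffer cells, hepatocytes and sinusoidal endothelium ranked lower. None of these lists was called with an estimated correlation, where the lowest adjusted p was 0.0525. That of Kupffer cells was not called by fry either (adjusted p = 0.123). Gpnmb, a membrane glycoprotein of lipid-laden macrophages, rose from 1.45 ± 0.780 to 407 ± 178 CPM (SD, n = 4 each), and Cd163, the haemoglobin scavenger receptor of resident macrophages, fell from 249 ± 118 to 2.85 ± 2.13 CPM. Vcam1, the adhesion molecule that binds leukocyte integrins, rose from 230 ± 15.1 to 434 ± 28.8 CPM. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 2444 genes changed, 1357 higher and 1087 lower in FFC, and 1534 of them by at least 2-fold, 1008 higher and 526 lower. The groups did not overlap for 2117 of the changed genes. Over all genes tested this was so for 20.7%, where chance gives 2.86%.

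**Figure D2:**
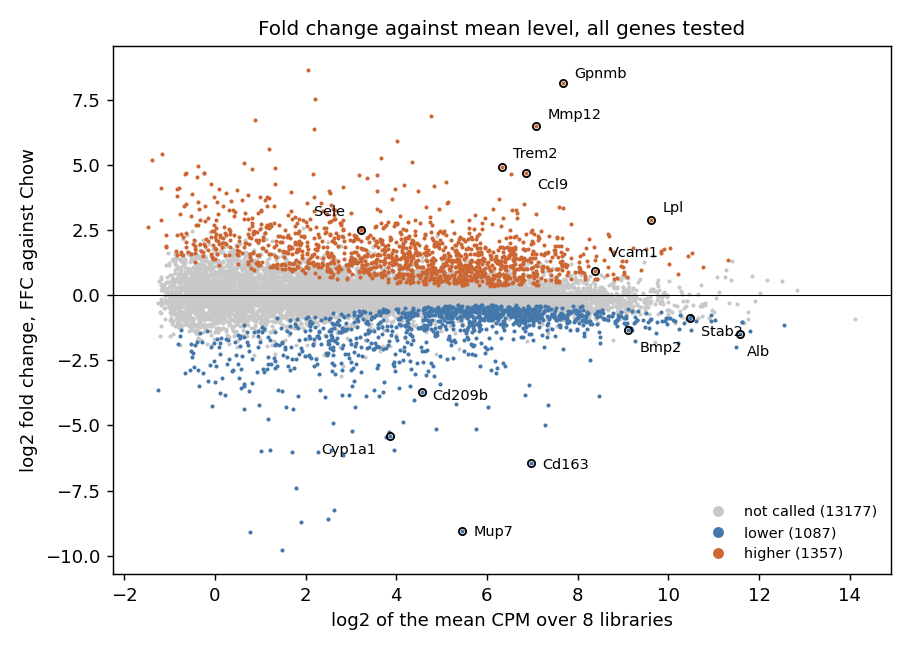
Log2 fold change of FFC against Chow (y axis) by the log2 mean CPM over 8 libraries (x axis) for the 15621 genes tested; orange points are the 1357 genes higher and blue points the 1087 genes lower in FFC by edgeR (adjusted p under 0.05), grey points the rest, and circles mark labelled genes. Gpnmb, Mmp12 and Trem2 stand at the top and Mup7 and Cd163 at the bottom, while Vcam1 and Stab2 moved by less than 2-fold.

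The 10 largest increases were Gpnmb, Atp6v0d2, Mmp12, Gdf3, Trem2, Ccl9, Slfn4, Dpep2, Ms4a4a and Fcrls, with log2 fold changes from 4.50 to 8.14. Several of these genes are markers of macrophages. Mmp12, a macrophage elastase, rose by a log2 fold change of 6.51 (SE 0.42, adjusted p = 0.000108, edgeR), and Trem2, a lipid-sensing receptor, by 4.93 (SE 0.41, adjusted p = 0.00033, edgeR). The rise of Slfn4 was uneven, 177 ± 233 CPM in FFC against 7.07 ± 1.5 in Chow (SD, n = 4). It stood at 524 CPM in FFC replicate 4 and at 36.7 to 90.8 in the other FFC libraries. Without single libraries its log2 fold change ran from 3.12 to 5.02. The 10 largest decreases were Mup7, Cyp2c54, Slco1a1, Cd163, Mup17, Mup15, Mup11, Cyp2c50, Cyp1a1 and Elovl3, from -9.04 to -5.24. The Mup genes encode major urinary proteins made by hepatocytes, Cyp2c54 and Cyp2c50 are liver cytochromes P450, and Slco1a1 is a liver organic anion transporter. Mup and Cyp2c genes are near-identical copies, so their single values are uncertain. Cyp2c54 had 776 counts over the Chow libraries and 2 over the FFC libraries, a ratio of 483 with an exact 95% interval of 133 to 3991, and Slco1a1 had 850 and 3, a ratio of 352 (120 to 1712). Cyp1a1, a target of the aryl hydrocarbon receptor, fell by 5.4 on the log2 scale (SE 0.35, adjusted p = 0.000108, edgeR), from 28.5 ± 5.33 to 0.661 ± 0.326 CPM (SD, n = 4).

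Adhesion molecules of endothelium moved in both directions. Of 17 measured members, 4 rose and 5 fell (5 and 6 adjusted over the list alone), and the list as a whole was not called (camera adjusted p = 0.941, adjusted p = 0.985 with an estimated correlation), with a median of -0.27 and a mean of 0.07. Vcam1 (ENSMUSG00000027962, chromosome 3, 116110020 to 116129688, mm10, protein-coding) rose by a log2 fold change of 0.92 (SE 0.13, adjusted p = 0.00211, edgeR), with all 4 FFC libraries above all 4 Chow libraries. Sele, the selectin induced on activated endothelium, rose by 2.5 (SE 0.37) from a low 2.77 ± 1.76 CPM, and Ackr1, the chemokine-binding receptor of venules, by 1.57 (SE 0.24). Cldn5, the tight-junction claudin of endothelium, fell by 1.46 on the log2 scale (SE 0.31), from 416 ± 39.5 to 151 ± 75.1 CPM. Pecam1, the pan-endothelial adhesion molecule, stood at 1333 ± 124 CPM in Chow and 999 ± 269 in FFC (log2 fold change -0.42, SE 0.21, adjusted p = 0.214, edgeR). The number that fell was 1 without any single library other than FFC replicate 2, and 7 without that library.

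**Figure D3:**
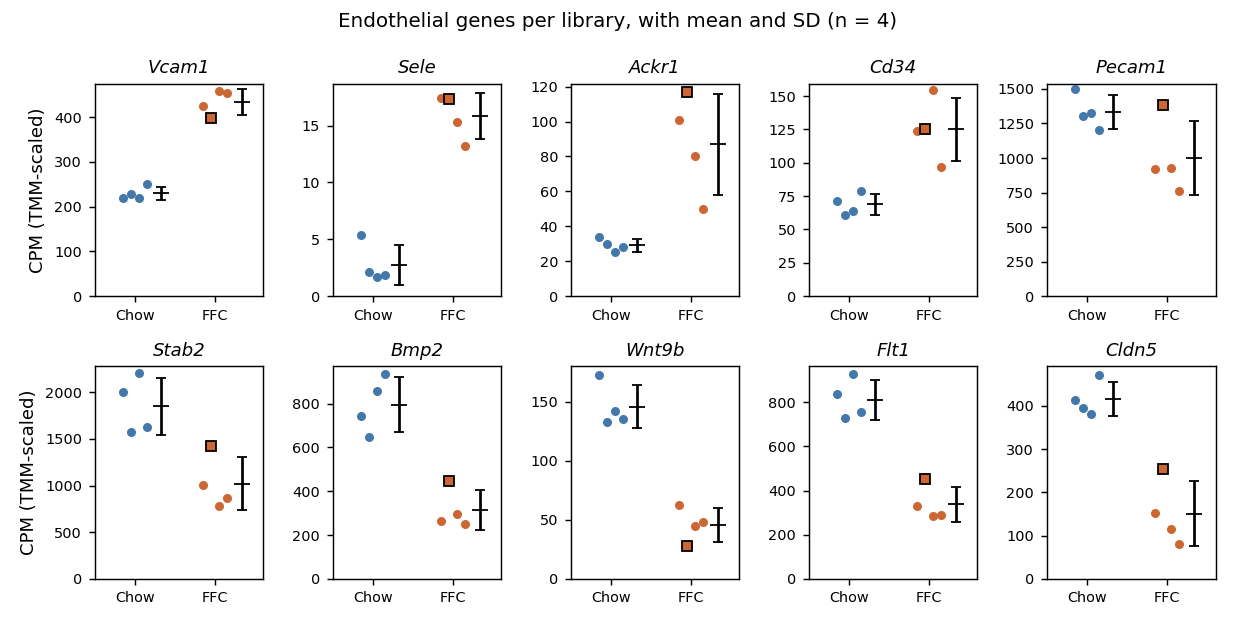
TMM-scaled CPM (y axes, from 0) of 10 endothelial genes in Chow (blue) and FFC (orange) libraries; points are single libraries, black squares mark FFC replicate 2, and bars give the mean ± SD (n = 4). Vcam1, Sele, Ackr1 and Cd34 were higher in all FFC libraries, Bmp2, Wnt9b, Flt1, Cldn5 and Stab2 were lower in all of them, and Pecam1 overlapped.

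The list of genes that mark the sinusoidal identity of these cells ranked lower. Of the 19 measured scavenger receptors and identity genes, 8 fell and none rose (15 fell and 1 rose adjusted over the list alone), with a median log2 fold change of -0.86 (camera adjusted p = 7.72e-08, adjusted p = 0.414 with an estimated correlation). Cd209b, a C-type lectin, fell by 3.73 on the log2 scale (SE 0.58), and Bmp2, an endothelial signal that acts on hepatocyte iron regulation, by 1.34 (SE 0.22). Stab2 (chromosome 10, 86841198 to 87008025), a hyaluronan scavenger receptor, fell by 0.86 (SE 0.23, adjusted p = 0.0338, edgeR), a call lost without any single library other than FFC replicate 2. It was also lost when scaled to pan-endothelial genes (-0.11, adjusted p = 0.555). Lyve1, another hyaluronan receptor, stood at 390 ± 72.7 CPM in Chow and 643 ± 208 in FFC (log2 fold change 0.72, SE 0.24, adjusted p = 0.0724, edgeR). The list's mean log2 CPM was 10.14 ± 0.03 in Chow, 9.96 in FFC replicate 2 and 8.74 to 9.03 in the other FFC libraries. That of the lipid-associated macrophage list was 7.67 in FFC replicate 2 and 8.43 to 8.75 in the others. The median of 25 pan-endothelial genes was -0.69, with 24 below 0. Without FFC replicate 2, 17 members of the sinusoidal list fell, and 2 fell without Chow replicate 2 or 3 or FFC replicate 1, 3 or 4.

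Markers of continuous endothelium, the set gained when sinusoids capillarize, did not move together. Of 21 measured, 5 rose and 4 fell (5 and 5 adjusted over the list alone, camera adjusted p = 0.483, adjusted p = 0.816 with an estimated correlation). Cd34 (chromosome 1, 194938819 to 194961279), a sialomucin of continuous capillaries, rose by a log2 fold change of 0.86 (SE 0.16, adjusted p = 0.0065, edgeR), and the tetraspanin Cd9 by 0.83 (SE 0.16). Cd9 is also in the list of lipid-associated macrophage markers, whose median was 2.64. Cav1, the coat protein of caveolae, fell by 0.69 on the log2 scale (SE 0.13). Scaled to pan-endothelial genes, its log2 fold change was 0.14 (adjusted p = 0.599). The number that fell was 2 without Chow replicate 1, 3 or 4 or FFC replicate 3 or 4, and 6 without FFC replicate 2. Markers of large vessels (3 rose and 3 fell of 18; 4 and 3 adjusted over the list alone, camera adjusted p = 0.928, adjusted p = 0.945 with an estimated correlation) and of lymphatic endothelium (1 rose and 1 fell of 10; 2 and 1 adjusted over the list alone, camera adjusted p = 0.827, adjusted p = 0.897 with an estimated correlation) were not called either. Of the markers of large vessels, 1 fell without Chow replicate 2, 3 or 4 or FFC replicate 1 or 4. Of the lymphatic markers, 2 rose and 2 fell without FFC replicate 2. For the lymphatic list the median, 0.49, and the camera direction, lower, differed in sign.

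Among 20 angiocrine factors, 6 fell and none rose (7 fell and 5 rose adjusted over the list alone, camera adjusted p = 0.021, adjusted p = 0.358 with an estimated correlation). Wnt9b (chromosome 11, 103727364 to 103749821), a Wnt ligand of central-vein endothelium, fell by 1.67 on the log2 scale (SE 0.23), Bmp6 by 1.36 (SE 0.23) and Kitl, the ligand of Kit, by 0.85 (SE 0.15). The angiocrine call was lost without Chow replicate 1 (highest adjusted p over the left-out libraries 0.0819), and 2 members rose without Chow replicate 4 or FFC replicate 2. Over the same libraries 25 pan-endothelial genes, chosen after seeing the data, had a median of -0.69, with 24 below 0 and 11 past the threshold, against -0.46 for the angiocrine list. The lipid-associated macrophage list had 2.64. Scaled to those genes, 7 angiocrine factors were higher and 4 lower. Of 12 pericentral genes, 5 fell, among them Wnt9b, Lhx6 and Kit, and 1 rose (6 and 1 adjusted over the list alone, camera adjusted p = 0.000388, adjusted p = 0.361 with an estimated correlation). None of the pericentral genes rose without any single library other than Chow replicate 1 or FFC replicate 4. With the same scaling 3 were higher and 2 lower. Periportal genes were split, 2 up and 2 down of 11 (2 and 2 adjusted over the list alone, camera adjusted p = 0.222, adjusted p = 0.70 with an estimated correlation). Ltbp4, a matrix protein that binds latent TGF-beta, fell by 1.46 on the log2 scale (SE 0.28). Without FFC replicate 2 the periportal list was called lower (camera adjusted p = 0.00739), with 7 members that fell. Of the periportal genes 1 fell without any single library other than FFC replicate 2 or 4, and 1 rose without Chow replicate 2, 3 or 4 or FFC replicate 3.

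Of 21 genes of VEGF and angiopoietin signalling, 6 fell and 2 rose (8 and 3 adjusted over the list alone, camera adjusted p = 0.03, adjusted p = 0.459 with an estimated correlation). Nrp1, a VEGF co-receptor, fell by 1.35 on the log2 scale (SE 0.21) and Flt1, VEGF receptor 1, by 1.26 (SE 0.19). Esm1, the tip-cell proteoglycan, rose by 1.61 (SE 0.31). Aplnr, the apelin receptor, rose by 2.36 (SE 0.54) from a low 0.581 ± 0.246 CPM, a call lost without FFC replicate 1 or 3. Flt4, VEGF receptor 3, did not pass (-0.71, adjusted p = 0.0953, edgeR). This list call was lost without Chow replicate 1, 2 or 3 or FFC replicate 1 or 3 (highest adjusted p 0.121), and with the replicate number as a block (adjusted p = 0.0528). The number of its members that fell was 2 without Chow replicate 1 or 3 or FFC replicate 1 or 3, and 11 without FFC replicate 2, and 1 rose without FFC replicate 3. Pan-endothelial genes had a median of -0.69, with 24 of 25 below 0, against -0.39 for this list, while the lipid-associated macrophage list had 2.64. Scaled to those genes, 9 members of this list were higher and 2 lower. Some members of this list are themselves among the 25 genes, which holds them near 0 after scaling by construction. In the program that laminar flow maintains through KLF2 and KLF4, 6 of 17 genes fell and 1 rose (7 and 1 adjusted over the list alone, camera adjusted p = 0.000149, adjusted p = 0.161 with an estimated correlation). Besides Cyp1a1, Slc9a3r2 fell by 1.28 on the log2 scale (SE 0.22), and Klf6 rose by 0.88 (SE 0.18). Klf2 itself fell by 0.55 (SE 0.16, adjusted p = 0.0451, edgeR) and Nos3, the endothelial nitric oxide synthase, by 0.65 (SE 0.18, adjusted p = 0.0415, edgeR). Scaled to pan-endothelial genes, an alternative chosen after seeing the data, neither passed, Klf2 at 0.23 (adjusted p = 0.34) and Nos3 at 0.10 (adjusted p = 0.674). Both of these calls were lost without any of Chow replicates 2, 3 and 4 or FFC replicates 1, 3 and 4, and that of Klf2 also without Chow replicate 1. Of the flow program, 2 members fell without FFC replicate 3 or 4 and 9 without FFC replicate 2, and with that scaling 4 were higher and 3 lower. Some members of the flow program, Pecam1 among them, are also scaling genes. Notch pathway genes were not called (2 rose and 1 fell of 16; 3 and 2 adjusted over the list alone, camera adjusted p = 0.933, adjusted p = 0.958 with an estimated correlation). Of the Notch genes 3 fell without FFC replicate 2. Hey1, a Notch target, rose by 1.05 (SE 0.20).

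Most markers of lipid-associated macrophages, monocytes and neutrophils rose steeply, and some of dendritic cells rose. Of 12 markers of lipid-associated macrophages, 10 rose (12 adjusted over the list alone), with a median log2 fold change of 2.64 (camera adjusted p = 5.36e-32, adjusted p = 0.0525 with an estimated correlation). Of 15 markers of monocytes and their macrophage progeny, 12 rose (14 adjusted over the list alone; median 2.17; camera adjusted p = 3.21e-19, adjusted p = 0.161 with an estimated correlation). Among them the chemokine receptors Cx3cr1 and Ccr2 rose by 3.69 (SE 0.30) and 3.29 (SE 0.27), to 143 ± 54.4 and 170 ± 59.2 CPM (SD, n = 4). Neutrophil genes rose in 11 of 12 cases (12 adjusted over the list alone, camera adjusted p = 3.3e-11, adjusted p = 0.176 with an estimated correlation), with Csf3r, the G-CSF receptor, at 142 ± 35.7 CPM in Chow and 684 ± 231 in FFC. Dendritic cell genes rose in 5 of 12 cases and fell in 1 (7 and 2 adjusted over the list alone, camera adjusted p = 0.00193, adjusted p = 0.361 with an estimated correlation), with Itgax up by 3.52 (SE 0.36) and the growth factor receptor Flt3 by 2.67 (SE 0.37). Itgax is also in the list of lipid-associated macrophage markers. No dendritic cell gene fell without Chow replicate 1 or 2 or FFC replicate 1, 3 or 4, and 2 fell without FFC replicate 2. The mean log2 CPM of the lipid-associated macrophage list was 4.63 to 5.33 in Chow, 7.67 in FFC replicate 2 and 8.43 to 8.75 in the other FFC libraries.

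Some genes of resident Kupffer cells fell. Of 16 measured, 6 fell and none rose (7 adjusted over the list alone; median -0.67; camera adjusted p = 0.000589, adjusted p = 0.529 with an estimated correlation). Cd163 (chromosome 6, 124304651 to 124330527) fell by 6.45 on the log2 scale (SE 0.61, adjusted p = 0.000558, edgeR) and Timd4, a phosphatidylserine receptor of embryo-derived Kupffer cells, by 2.98 (SE 0.56). Marco, a scavenger receptor, fell by 3.83 (SE 0.95), a call lost without FFC replicate 3 or 4. The list's mean log2 CPM was 8.34 to 9.38 in Chow, 7.02 to 7.25 in FFC replicates 2 to 4 and 8.38 in FFC replicate 1, within the Chow range. Marco in that library lay far above the other FFC libraries. The list was not called by fry (adjusted p = 0.123). Without FFC replicate 3 or 4, 2 members of the list fell. With scaling to pan-endothelial genes, 3 Kupffer cell genes were lower and 5 higher.

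**Figure D4:**
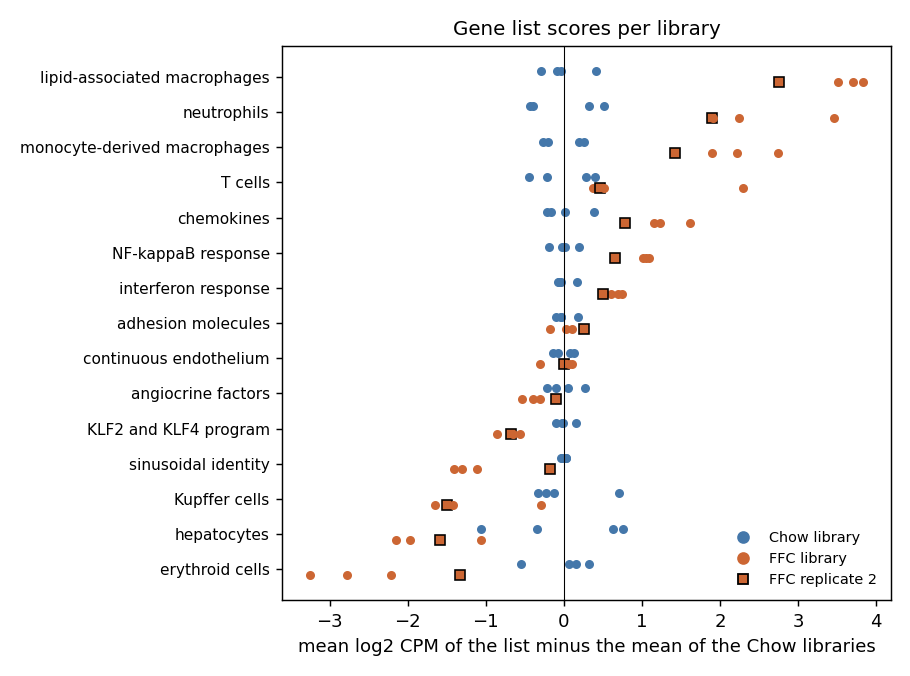
Mean log2 CPM of the members of 15 gene lists in each library, minus the mean of the 4 Chow libraries (x axis); blue points are Chow and orange points FFC libraries, and the black-edged square is FFC replicate 2. All FFC libraries lie above all Chow libraries for lipid-associated macrophages, neutrophils and monocyte-derived macrophages, and the sinusoidal identity score of FFC replicate 2 lies near Chow.

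Lists of inflammatory signalling ranked higher along with those of lipid-associated macrophages, monocytes and neutrophils. Of 20 chemokines, 9 rose and 2 fell (14 and 2 adjusted over the list alone, camera adjusted p = 1.48e-09, adjusted p = 0.161 with an estimated correlation). Ccl9 rose by 4.69 (SE 0.31), and Ccl2, the chemokine that draws monocytes through Ccr2, by 2.69 (SE 0.23), from 3.67 ± 0.999 to 23.7 ± 3.83 CPM (SD, n = 4). The fall was in Cxcl13 and Ccl24, both named outside the rule after their values were seen, of which Cxcl13, the B-cell attractant, fell by 5.14 on the log2 scale (SE 0.72). The number that fell was 1 without any single library other than Chow replicate 1 or FFC replicate 2. NF-kappaB and cytokine response genes rose in 13 of 20 cases (14 adjusted over the list alone, camera adjusted p = 1.42e-10, adjusted p = 0.176 with an estimated correlation), with Ptgs2, the inducible cyclooxygenase, up by 2.75 (SE 0.30) and Tnf by 2.68 (SE 0.31). Interferon-responsive genes rose in 16 of 30 cases (21 adjusted over the list alone, camera adjusted p = 1.53e-08, adjusted p = 0.0525 with an estimated correlation) by smaller amounts, with Oasl2 up by 1.35 (SE 0.16) and Rsad2 by 0.74 (SE 0.12), and in 10 cases without Chow replicate 1, 2 or 3.

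MHC class II genes rose in 5 of 15 cases (9 adjusted over the list alone; median 1.22; camera adjusted p = 0.000268, adjusted p = 0.459 with an estimated correlation), with H2-Aa at 712 ± 436 CPM in Chow and 2210 ± 936 in FFC. By fry the list was not called (adjusted p = 0.0626). Its mean log2 CPM was 6.75 in Chow replicate 4, apart from 5.56 to 5.73 in the other Chow libraries, and 6.36 to 7.48 in FFC. Over the same libraries the medians of the dendritic cell, monocyte and lipid-associated macrophage lists were 0.82, 2.17 and 2.64. None of the 5 was called without any single library other than Chow replicate 4 or FFC replicate 2, and 10 were called without Chow replicate 4. MHC class I genes were not called (1 fell of 17; none adjusted over the list alone, camera adjusted p = 0.18, adjusted p = 0.816 with an estimated correlation), though the list was called without Chow replicate 2 (adjusted p = 0.0427). None of them fell without any single library other than FFC replicate 2, and 1 rose without Chow replicate 4 or FFC replicate 2. Its most abundant member, B2m, stood at 4123 ± 597 and 3559 ± 549 CPM (log2 fold change -0.21, SE 0.21, adjusted p = 0.545, edgeR). Immediate early genes, which also respond to cell dissociation, rose in 14 of 24 cases and fell in 2 (15 and 2 adjusted over the list alone, camera adjusted p = 6.67e-08, adjusted p = 0.361 with an estimated correlation). Atf3 rose by 1.87 (SE 0.25) and Nr4a1 by 1.74 (SE 0.24). The 2 that fell were the heat shock genes Hspa1a and Hspa1b, named outside the rule, which were high in Chow replicates 3 and 4 and whose calls were lost without any single library other than Chow replicate 1 or 2.

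Some genes of lipid uptake and sterol efflux rose and a few of cholesterol synthesis fell. Among 26 PPAR targets and genes of fatty acid uptake and storage, 5 rose (10 rose and 2 fell adjusted over the list alone, camera adjusted p = 0.00753, adjusted p = 0.358 with an estimated correlation). Lpl, lipoprotein lipase, rose by 2.91 (SE 0.36) from 186 ± 45.4 to 1394 ± 568 CPM (SD, n = 4), and Pparg by 1.55 (SE 0.16). Lpl is also in the list of lipid-associated macrophage markers. In FFC replicates 1 to 4 it stood at 1639, 593, 1909 and 1434 CPM, where that list's mean log2 CPM was 8.63, 7.67, 8.75 and 8.43. Among 16 LXR targets, 3 rose (5 adjusted over the list alone, camera adjusted p = 0.00105, adjusted p = 0.361 with an estimated correlation), with the cholesterol exporter Abca1 up by 1.80 (SE 0.19). Among 24 genes of cholesterol synthesis, 3 fell (3 adjusted over the list alone, camera adjusted p = 0.000417, adjusted p = 0.459 with an estimated correlation), of which Insig1, an inhibitor of SREBP processing, fell by 1.2 on the log2 scale (SE 0.19). Scaled to pan-endothelial genes, none of the 3 passed, with Insig1 at -0.34 (adjusted p = 0.275), Msmo1 at 0.17 (adjusted p = 0.553) and Sc5d at 0.36 (adjusted p = 0.245). Genes of fatty acid and triglyceride synthesis were not called (1 rose and 4 fell of 18; 1 and 4 adjusted over the list alone, camera adjusted p = 0.212, adjusted p = 0.70 with an estimated correlation), except without Chow replicate 1 (adjusted p = 0.0476). Of these, 2 fell without Chow replicate 2, 3 or 4 or FFC replicate 1, 3 or 4, and none rose without any single library other than FFC replicate 2. Without single libraries the counts of the first 3 lists ran from 2 to 6 (lowest without Chow replicate 2 or 3 or FFC replicate 3, highest without FFC replicate 2 or 4), from 2 to 6 (highest without FFC replicate 2) and from 1 to 4 (lowest without Chow replicate 1 or 3 or FFC replicate 3 or 4). Of the PPAR targets 2 fell without Chow replicate 1 or FFC replicate 2.

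Lysosome and endocytosis genes rose in 6 of 25 cases (15 rose and 1 fell adjusted over the list alone, camera adjusted p = 4.58e-06, adjusted p = 0.364 with an estimated correlation), with the tetraspanin Cd63 up by 2.11 (SE 0.21), and in 12 cases without FFC replicate 2. Cd63 and Atp6v0d2, another of the 6, are also in the list of lipid-associated macrophage markers. Cd63 stood at 266, 147, 287 and 206 CPM in FFC replicates 1 to 4, where that list's mean log2 CPM was 8.63, 7.67, 8.75 and 8.43. Lysosome genes rose in 4 cases without Chow replicate 2 or 3 or FFC replicate 1 or 3, and fell in 2 without FFC replicate 2. Glycolysis genes rose in 5 of 19 cases (5 adjusted over the list alone, camera adjusted p = 0.000911, adjusted p = 0.459 with an estimated correlation), with Pfkfb4 up by 2.16 (SE 0.25) and the lactate exporter Slc16a3 by 2.01 (SE 0.31). The count was 3 without Chow replicate 2 or 3 or FFC replicate 1, and 1 glycolysis gene fell without FFC replicate 2. None of 26 oxidative phosphorylation genes passed the test singly (none adjusted over the list alone), while the list ranked lower (median -0.27; camera adjusted p = 0.009, adjusted p = 0.70 with an estimated correlation), a call lost without Chow replicate 1 or FFC replicate 4 (highest adjusted p 0.0943) and not made by fry (adjusted p = 0.19). Nor was it made with scaling to pan-endothelial genes (adjusted p = 0.666). Proliferation genes rose in 8 of 32 cases (12 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.000133, adjusted p = 0.529 with an estimated correlation), with the kinesins Cenpe up by 1.69 (SE 0.34) and Kif20a by 1.16 (SE 0.24), and in 2 cases without Chow replicate 3 or FFC replicate 1 or 3.

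Extracellular matrix and remodelling genes rose in 10 of 30 cases and fell in 2 (12 and 4 adjusted over the list alone, camera adjusted p = 1.5e-06, adjusted p = 0.161 with an estimated correlation). Besides Mmp12, which is also in the list of lipid-associated macrophage markers, the collagenase Mmp13 rose by 4.10 (SE 0.32), the protease inhibitor Timp1 by 3.01 (SE 0.31) and Col15a1 by 2.94 (SE 0.34). Of the matrix genes 1 fell without Chow replicate 1, 2 or 3 or FFC replicate 3. The list for TGF-beta response and endothelial-to-mesenchymal transition was not called (6 rose and 2 fell of 29; 8 and 7 adjusted over the list alone, camera adjusted p = 0.508, adjusted p = 0.816 with an estimated correlation). Its median, -0.18, and its mean, 0.29, differed in sign. Tgfbr1, a TGF-beta receptor, rose by 1.62 (SE 0.22). Coagulation genes were not called (3 rose and 2 fell of 17; 4 and 2 adjusted over the list alone, camera adjusted p = 0.89, adjusted p = 0.945 with an estimated correlation). Their median, -0.18, and mean, 0.07, differed in sign, and Ptgis, prostacyclin synthase, fell by 2.61 on the log2 scale (SE 0.33). Genes of the unfolded protein response (3 rose and 4 fell of 22; 3 and 5 adjusted over the list alone, camera adjusted p = 0.294, adjusted p = 0.857 with an estimated correlation) and NRF2 targets (2 rose and 3 fell of 21; 2 and 3 adjusted over the list alone, camera adjusted p = 0.697, adjusted p = 0.922 with an estimated correlation) were not called. Of the latter, Slc7a11, the cystine transporter, rose by 4.37 (SE 0.35) and Gstm1 fell by 1.13 on the log2 scale (SE 0.13). The 4 decreases of the unfolded protein response list were all lost without Chow replicate 3 or 4 or FFC replicate 1 or 3, and the list was called without Chow replicate 2 (adjusted p = 0.00991). Without FFC replicate 2, 10 of the TGF-beta genes rose and 8 fell, and 5 of the coagulation genes rose and 4 fell, while 1 NRF2 target fell without FFC replicate 3 or 4. None of the TGF-beta genes fell without Chow replicate 1 or FFC replicate 1 or 3, and 1 coagulation gene fell without Chow replicate 1, 2 or 4 or FFC replicate 3 or 4.

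The hepatocyte list ranked lower. Of 24 measured, 14 fell and none rose (19 adjusted over the list alone; median -1.55; camera adjusted p = 6.46e-11, adjusted p = 0.361 with an estimated correlation). Alb, serum albumin (chromosome 5, 90460889 to 90476603), fell by 1.5 on the log2 scale (SE 0.38, adjusted p = 0.0249, edgeR), from 4501 ± 2089 to 1587 ± 389 CPM, a call lost without Chow replicate 3 or 4 or FFC replicate 1 or 4. Mup3 fell by 4.19 (SE 0.48) and Cps1, the first enzyme of the urea cycle, by 4.19 (SE 0.60). The list's mean log2 CPM ranged from 6.17 to 7.99 in Chow and from 5.08 to 6.17 in FFC. The number that fell was 6 without Chow replicate 3 or 4 or FFC replicate 1 or 4. Scaled to pan-endothelial genes, 9 were lower and 1 higher. Erythroid genes fell in 5 of 6 cases (5 adjusted over the list alone; median -2.66; camera adjusted p = 4.98e-06, adjusted p = 0.176 with an estimated correlation), with Alas2, which starts haem synthesis in erythroid cells, down from 9.21 ± 0.368 to 1.87 ± 1.06 CPM (SD, n = 4).

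T cell markers ranked higher (1 rose of 15; 4 adjusted over the list alone, camera adjusted p = 0.0139, adjusted p = 0.70 with an estimated correlation), a call lost without FFC replicate 3 (adjusted p = 0.0673) and not made by fry (adjusted p = 0.267) or with the macrophage score as a covariate (adjusted p = 0.0886). The number that rose was 0 without any single Chow library and 4 without FFC replicate 2. Cholangiocyte genes rose in 3 of 13 cases (3 adjusted over the list alone, camera adjusted p = 0.00314, adjusted p = 0.604 with an estimated correlation), with Tspan8 up by 1.79 (SE 0.34), and fry did not call the list (adjusted p = 0.162). Platelet genes rose in 1 of 12 cases, Pf4, by 1.52 (SE 0.28; 1 adjusted over the list alone, camera adjusted p = 0.0355, adjusted p = 0.684 with an estimated correlation), and this list call was lost without Chow replicate 1 or 3 or FFC replicate 2 or 3 (highest adjusted p 0.34) and not made by fry (adjusted p = 0.152) or with the replicate number as a block (adjusted p = 0.0521). It was not made without Chow replicates 3 and 4 together (adjusted p = 0.134). Scaled to pan-endothelial genes, the T cell (adjusted p = 0.363), cholangiocyte (adjusted p = 0.11) and platelet lists (adjusted p = 0.0785) were not called. Markers of NK cells (none changed of 13, none adjusted over the list alone, camera adjusted p = 0.992, adjusted p = 0.998 with an estimated correlation), B cells (1 rose of 12, none adjusted over the list alone, camera adjusted p = 0.644, adjusted p = 0.943 with an estimated correlation; called without FFC replicate 3, adjusted p = 0.0486) and plasma cells (2 rose and 1 fell of 12; 4 and 2 adjusted over the list alone, camera adjusted p = 0.80, adjusted p = 0.945 with an estimated correlation) were not called. The B cell call made without FFC replicate 3 was lower, with a median of -0.45. No B cell gene rose without any single library other than Chow replicate 4 or FFC replicate 2. Of the plasma cell genes 1 rose without Chow replicate 1, 2 or 4 or FFC replicate 3 or 4, and 2 fell without Chow replicate 1. Stellate cell and fibroblast genes were not called either (3 rose and 1 fell of 18; 5 and 1 adjusted over the list alone, camera adjusted p = 0.204, adjusted p = 0.844 with an estimated correlation), though Rgs5, a pericyte marker, rose from 44.6 ± 18.5 to 246 ± 37.3 CPM and Col1a1 by 2.40 (SE 0.42). Without Chow replicate 1 or FFC replicate 4 the stellate list was called higher (lowest adjusted p 0.00135). Of its members 5 rose without Chow replicate 1, and none fell without FFC replicate 3. With too few measured members for a list test, the mesothelial gene Gpm6a had a log2 fold change of 0.51 (SE 0.18, adjusted p = 0.086, edgeR), and of mast cell and basophil genes Hdc rose by 1.23 (SE 0.18) and Kit fell by 0.94 on the log2 scale (SE 0.19).

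In all, 28 of the 44 lists were called by camera, 18 higher and 10 lower, 22 by fry and none with an estimated correlation, where the lowest adjusted p was 0.0525. The number of changed genes was 1536 without Chow replicate 2, 1508 without Chow replicate 3, 1528 without FFC replicate 1 and 1427 without FFC replicate 3, and 3581 without FFC replicate 2; it was 265 with the hepatocyte score and 1145 with the macrophage score as a covariate. Scaled by library size alone, 1694 genes were higher and 823 lower, and scaled to 25 pan-endothelial genes, an alternative chosen after seeing the data, 9148 were higher and 279 lower. With that scaling 9 adhesion molecules were higher and 1 lower, 8 and 1 markers of large vessels, 7 and 0 of continuous endothelium, and 7 and 0 genes of the unfolded protein response. Some genes of the adhesion and continuous endothelium lists are themselves among the 25, which holds them near 0 by construction.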

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

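The tests of an unchanged hepatocyte profile, of a lower endothelial share, of dilution by leukocyte RNA and of the scalings of Vcam1, and the scores and scalings added as alternatives, were chosen after the results had been seen. Single libraries lay far from the other 3 of their group in 27 of 420 groups of values (by Dixon's ratio at the 95% level), where chance gives about 1 in 20 groups, or 21, so the number itself is little above chance. Values are log2 CPM, with the range of the other 3 libraries in parentheses.

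In Chow replicate 4, 7 values stood apart, all high: the lists for interferon response at 5.74 (5.50 to 5.53), MHC class II at 6.75 (5.56 to 5.73) and lysosome at 7.96 (7.56 to 7.60), and the genes Ctss at 9.95 (8.85 to 9.02), Itgax at 4.81 (3.81 to 3.94), Lck at 4.94 (3.87 to 4.01) and Ptgis at 4.34 (3.14 to 3.23). In FFC replicate 2, 4 genes were low, Ptgs2 at 7.53 (8.83 to 8.92), Tgfbr1 at 7.10 (8.01 to 8.10), Itgax at 6.59 (7.86 to 8.03) and Tspan8 at 6.60 (7.68 to 7.87), while Ifi44 at 7 (6.63 to 6.68) and the periportal list at 8.03 (7.35 to 7.45) were high. In FFC replicate 3 the T cell list at 4.15 (2.23 to 2.37), the NK cell list at 4.74 (3.42 to 3.61), the unfolded protein response list at 6.74 (6.52 to 6.54), Chil3 at 6.21 (4.93 to 5.08) and Cyp2c54 at -2.40 (-3.30 in the others, the value of 0 counts) were high. FFC replicate 1 was high in the Kupffer cell list at 8.38 (7.02 to 7.25) and in Marco at 5.60 (1.80 to 2.15), and FFC replicate 4 was low in the oxidative phosphorylation list at 6.24 (6.72 to 6.73) and in B2m at 11.42 (11.86 to 11.94). Low values in Chow were those of Ccl9 at 2.85 (3.18 to 3.25) and Slfn4 at 2.30 (2.95 to 3.02) in replicate 3, Skil at 5.99 (6.26 to 6.30) in replicate 2 and Cftr at 0.92 (2.42 to 2.71) in replicate 1.

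The 8 libraries can be split into 4 and 4 in 35 ways. Of these, 1, the real split, gave 2444 changed genes, and the highest other gave 0. Every other split mixes the diets, so a difference between diets adds to the spread within its groups and leaves few calls. The real split ranked first of 35, the most this test can show, and chance is not excluded. For lists too, 1 of the 35 splits gave as many as 28, the real one, but the highest other gave 25 and the median of the others was 18.5. Other splits with unequal numbers of the diets keep part of the diet contrast, and they gave 17 to 25 lists. Splits with equal numbers of both diets gave 8 to 23. Camera at the preset correlation thus calls many lists in balanced splits of these libraries too, and the number of lists called says little by itself about the diet.

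Vcam1 was higher in FFC, and RNA of other cells or the scaling between libraries could lie behind this. Under RLE, upper-quartile, library-size and pan-endothelial scaling its log2 fold change was at least 0.90 and past the threshold. Over the genes tested, these scalings shifted log2 fold changes by medians of 0.002, -0.016, 0.109 and 0.814. None could thus have lowered Vcam1 by much, so the test cannot decide about scaling. With the score of Kupffer and monocyte genes as a covariate it was 0.87 (SE 0.14, adjusted p = 0.00957, edgeR), but that score differed by only 0.38 between the groups, since its Kupffer and monocyte genes moved in opposite directions, so this excludes little beyond that score. With the score of lipid-associated macrophage genes it was 0.22 (SE 0.56, adjusted p = 0.953, edgeR), and as the score follows the groups at r = 0.98, RNA from such macrophages and a rise within endothelium cannot be told apart here. In FFC replicates 1 to 4 Vcam1 stood at 425, 397, 459 and 454 CPM, where that list's mean log2 CPM was 8.63, 7.67, 8.75 and 8.43.

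Hepatocyte genes were lower in FFC, by 1.69 in their mean score. Less hepatocyte RNA of an unchanged profile is argued against, since 11 of the 24 members differed between the diets after each library's list mean was subtracted. Among these, Cps1 and Mup3 each had a log2 fold change of -4.19, against -1.20 for Ttr and -0.98 for Fga. Trf at -0.05 and Hp at 0.57 also differed, but RNA of other cells could hold them up, which was not tested. The same could hold for other members that fell less than the list mean. Any member held up in this way also pushes the rest below that mean, which weakens the count of 11. Carry-over in Chow replicates 3 and 4 alone stays open: without both, 5 members were still lower, between the bounds set for and against it. The list as a whole was still called lower without both, by camera at its preset correlation. A lower hepatocyte share together with a changed hepatocyte profile under the diet was not tested apart.

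Sinusoidal endothelial genes were lower in FFC. A lower endothelial share with other cell types alike is argued against only as to the other cell types. The median of the monocyte list lay 3.71 above that of the hepatocyte list. Neither list is endothelial, so this test cannot decide whether the endothelial share itself was lower. Dilution of endothelial RNA by leukocyte RNA stays open for the list as a whole. Scaled to 25 pan-endothelial genes, whose median was -0.69, the list's median was -0.11, which met the bound first set for dilution. However, its members passed the threshold in both directions, with Lyve1 at 1.45 and Clec1b at 0.71 higher. The condition that they do not was added to the prediction only after the median was known. Of the 8 members that fell, 3 were still lower, Dnase1l3 at -0.71, Cd209b at -3.17 and Bmp2 at -0.60. Stab1, Stab2, Mrc1, Oit3 and Gpr182 were not. That met the bound set against dilution as the whole account for them. As the 8 were picked for having fallen in these same libraries, the test decides little. The scaling assumes that pan-endothelial genes do not respond to the diet, which is doubtful for some of the 25. Their log2 fold changes ran from -1.58 (Exoc3l2, SE 0.26) to 0.02 (Bcl6b, SE 0.17). Scaled, Exoc3l2 was still lower (-0.86, adjusted p = 0.00768, edgeR). A response shared by these genes cannot be checked here, so a loss of endothelial expression in general stays open as the biological alternative.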

How the results depend on the processing

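Scaling to pan-endothelial genes, leaving out Chow libraries 3 and 4, and the lipid-associated macrophage score were chosen after seeing the data; for the changes below the cause was not tested unless given. Of 2444 changed genes (1357 higher, 1087 lower), none turned sign with a call under any alternative. RLE factors gave 2448, upper-quartile factors 2443, no filter 2360, a 1 CPM filter 2323, removal of cell type markers 2373 and limma voom 2384. The count was 265 (184 higher, 81 lower) with the hepatocyte score, which follows the groups at r = -0.81, and 1145 (700, 445) with the macrophage score. It was 1168 (847, 321) without Chow libraries 3 and 4, which leaves fewer samples, and 9427 (9148, 279) scaled to pan-endothelial genes, which shifts the log2 fold changes by a median of 0.81. A 2-fold minimum gave 1534 (1008, 526) and a test against 1.2-fold 1655 with 633 lower, stricter by construction. DESeq2 called 3550, of which 1651 lower. Without single libraries the counts ran from 1427 to 3581 (higher 880 to 1926, lower 547 to 1655), lowest without FFC replicate 3 and highest without FFC replicate 2. With the lipid-associated macrophage score edgeR called 0 genes (0 higher, 0 lower; 1282 at an unadjusted p under 0.05; DESeq2 and voom were not run with it); of 150 named genes called without it, 72 changed sign and 0 were called, with a median SE of 1.04 against 0.29. At r = 0.98 it cannot be separated from the diet, and it was restricted to the gene counts and Vcam1 after its results for the named genes and lists had been looked at. Of the 28 lists called, 0 were called with an estimated correlation (0 higher, 0 lower) and 22 by fry. Pan-endothelial scaling lost 4 (T cells, cholangiocytes, platelets, oxidative phosphorylation), the replicate block 2 (VEGF, platelets), the hepatocyte score 1 (hepatocytes), the macrophage score 1 (T cells) and leaving out Chow libraries 3 and 4 lost 1 (platelets). Without single libraries 24 to 28 of them were still called, 24 without Chow replicate 1 and 25 without FFC replicate 3, and 26 to 29 lists in all. With the hepatocyte score the unfolded protein response list turned to 0.49 and the NK cell list to 1.08. Pan-endothelial scaling turned the log2 fold changes of Atp5a1 to 0.66, Atp5b 0.66, B2m 0.57, Cav1 0.14, Clec1b 0.71, Dnajb9 0.003, Dnajc3 0.10, Fads1 0.057, Gja5 0.24, Gpr126 0.35, Hes1 0.17, Klf2 0.23, Lpin1 0.33, Msmo1 0.17, Nos3 0.10 and Sc5d 0.36. With that scaling only Atp5a1, Atp5b, B2m and Clec1b passed the threshold, none of which had passed it before. The others lost their calls and were not called higher. Over all filtered genes the first component held 52.3%. The replicate number as a block gave 1981 genes. Correlations of the deviations of libraries with the same number were 0.37, -0.33, 0.48 and -0.24. Not every sample correlated best with its own number, and the numbers are not taken to pair the samples. Chow replicates 1 and 2 correlated with FFC replicates 1 and 4 at 0.29 to 0.38. Chow replicates 3 and 4 correlated with FFC replicates 2 and 3 at 0.17 to 0.48. All other pairs were negative, from -0.43 to -0.24. Libraries of both diets thus varied along a shared axis, whose source was not tested. At this depth and 4 libraries per group, 4.0% of simulated 1.5-fold changes were recovered.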

Other observations

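The genes in this part were chosen after their values were seen. Of the changed genes, 2180 are neither in a list nor named by the rule, 1194 higher and 986 lower in FFC. Il1rn, the antagonist of the interleukin-1 receptor, rose from 33.9 ± 7.11 to 352 ± 105 CPM (SD, n = 4; log2 fold change 3.38, SE 0.26, adjusted p = 0.000204, edgeR). Irg1, the enzyme that makes itaconate in activated macrophages, rose by 3.11 (SE 0.43), Clec4e, a C-type lectin of myeloid cells, by 3.18 (SE 0.35), and Lcn2, an iron-siderophore carrier, by 2.52 (SE 0.33). Tiam1, a Rac exchange factor, fell from 59.2 ± 7.55 to 10.8 ± 1.31 CPM (log2 fold change -2.46, SE 0.15, adjusted p = 0.000108, edgeR). Ehd3, an endocytic ATPase, fell from 4565 ± 400 to 1156 ± 564 CPM and Ppap2b, a lipid phosphate phosphatase, from 1845 ± 233 to 521 ± 214 CPM. Htra1, Lifr, Hpgd and Fcna fell as well, by 2.35, 1.34, 1.42 and 2.47 on the log2 scale. Scaled to pan-endothelial genes, the decreases named in this paragraph all stayed past the threshold. Ehd3 was then at -1.29 (adjusted p = 0.000788, edgeR) and Lifr at -0.62 (adjusted p = 0.0133, edgeR). As these genes were picked for having fallen, this decides little about dilution.

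Hspa1a stood at 6.93, 3.85, 71.5 and 145 CPM in Chow replicates 1 to 4, and Hsph1 at 45.2, 65.4, 322 and 520 CPM. In FFC Hspa1a stood at 5.33 ± 1.57 and Hsph1 at 88.4 ± 37 CPM (SD, n = 4), and Hsph1 did not pass the test (log2 fold change -1.43, SE 0.69, adjusted p = 0.195, edgeR). The mean log2 CPM of the hepatocyte list was 6.17, 6.89, 7.86 and 7.99 in the same 4 Chow libraries.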
